A study of Mus musculus with 8 samples.

How the data were processed

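RNA of sorted B cells was hybridised to 8 Affymetrix mouse arrays, 2 for each of 4 groups, with total RNA extracted by RNAzol and biotin-labelled by the standard Affymetrix protocol per the labels. The deposited values are intensities on a linear scale, and the software and scaling the authors used to make them are not given in the sources used here. They are whole numbers, 30.1% of them 0 or below, and the mean of each array after dropping the 2% lowest and 2% highest values is about 200.2. From this the values were read as scaled signals with background or mismatch signal subtracted. Each array's values were used as deposited, with no further normalization.

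Values under a floor were set to the floor and log2 was taken. The floor planned before the data were examined, the 30th percentile of all values, turned out to be 0 and has no log, so the 50th percentile, 81, which had been listed as an alternative, became the floor. Probe sets above this percentile on at least 2 arrays were kept, after 66 control probe sets were set aside, which left 7253 of 12488. Of all probe sets, 10855 name 1 gene, 396 several and 1237 none in the probe annotation. Gene positions are not analysed here. A fold with 1 or more arrays of its dimmer side at the floor is a lower bound and is given as at least that fold, and a log2 difference of a named gene likewise as at least, or if negative at most, its value. Array data carry no counts, so the number of arrays sets the precision.

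The tests were made in limma 3.58.1 under R 4.3.3, with 1 linear model of the 4 groups on all 8 arrays, empirical Bayes variances (4 residual degrees of freedom, 2.20 from the prior) and Benjamini-Hochberg adjustment over all probe sets tested in each comparison, at 0.05. The 7 comparisons were TI day 4 with TD day 4, TD day 10 with TD day 4, TI day 4 with TD day 10, the mean of the germinal centre groups with resting, and each germinal centre group with resting. Tests are two-sided. Before the data were examined, 20 lists of B cell genes and pathways and 11 lists of markers of other cells and of sorting stress were fixed. Of their 564 genes 371 were measured. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the lists of its kind. With the estimated correlation 0 of the 20 lists passed in each of the 7 comparisons. A gene with several probe sets is represented in a list by its brightest.

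Named genes follow a rule fixed before the data were examined. It takes the 10 largest rises and falls per comparison among called probe sets with 1 gene symbol and no overlap between the arrays, and, where fewer than 3 passed in a direction, the 5 with the smallest p. It adds the 4 members of each list with the smallest p, Bcl6 and Mki67 as checks of the sort, and the immunoglobulin constant region genes. The text names part of these genes. Shared calls were compared with 100 simulations without any effect. In these, as many probe sets as were called in the data were taken per comparison. They were those with the smallest p, whether or not they passed the threshold.

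The method was tested on simulated data of the same size for TI day 4 against TD day 4. With 200 changed probe sets in each of 20 draws, 24.6% of 2-fold and 68.3% of 4-fold changes were found, with 97.5 calls on average, 4.70 of them false. A list of 20 genes shifted by 1 on the log2 scale was found in 20 of 20 draws, and an unchanged list was called in 1. Each probe set was drawn independently and without a floor. The draws therefore cannot show how the list test behaves when the genes of a list move together. The list of plasma cell differentiation and secretion, for example, had an estimated correlation of 0.256.

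The alternatives tried were quantile normalization, a common median, no filter or a stricter one, a replicate block, only the arrays compared, a trended and robust prior, an equal-variance test of each probe set alone, array weights, and leaving out each array in turn. Others were chosen after seeing the data: floors at the 40th and 60th percentiles, a pseudocount in place of the floor, the 3' to 5' ratio of the Gapdh control as a covariate, a crossed replicate block, and leaving out markers of other cells or immunoglobulin probe sets. The deviations of arrays with the same replicate number correlated between -0.217 and 0.121 across groups, so no pairing by number was seen. Whether arrays with the same number were processed together is not known.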

Results

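Gene expression was measured on 8 arrays of an Affymetrix mouse platform, 2 for each of 4 populations of sorted B cells. Each array held RNA pooled from 4 to 10 F1 mice of the QM and C57BL/6 strains, and per the labels the replicates are biological. Resting B cells (GL7-negative, B220-positive) came from unimmunised mice, and germinal centre B cells (GL7-positive, B220-positive) from 3 kinds of response. The T-independent group (TI day 4) received 30 µg of the hapten NP on the polysaccharide Ficoll and was sorted on day 4. The first T-dependent group (TD day 4) was primed with 50 µg of the carrier protein and challenged 5 weeks later with 50 µg of soluble NP on that carrier. The second (TD day 10) received 50 µg of NP on the carrier in alum without earlier priming and was sorted on day 10. Array medians lay between 77 and 89 intensity units, and the number of arrays limits the precision of every value. The SD of the log2 difference between the 2 arrays of a group was 0.695 in resting, 0.501 in TD day 4, 0.552 in TD day 10 and 0.545 in TI day 4. On the first principal component (34.5% of the variance) both resting arrays lay apart from all germinal centre arrays, and on the second (24.2%) both TI arrays lay lowest. Of 12488 probe sets, 7253 were tested, with 5433 named genes.

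The first comparison set the mean of the germinal centre groups against resting B cells, so a call can rest mainly on 1 group. Stmn1, a regulator of microtubules, had the largest rise among the named genes and read 2343.5 ± 374 in TD day 4, 2297 ± 127 in TD day 10 and 2698 ± 159.8 in TI day 4 (SD, n = 2 each). Both resting arrays were under the floor, so the mean rise was at least 30.0-fold (adjusted p = 8.4e-05). The cell cycle kinase subunits Cks1b and Cks2 were at least 12.0-fold and 11.8-fold higher, the chromatin protein Hmgb2 15.1-fold, and Pclaf, which binds the replication clamp, 12.1-fold. Basp1 was at least 27.4-fold higher at 1 probe set, and at its other probe set the log2 difference was 0.26 ± 0.17 (SE) and did not pass. Anxa2 was at least 19.3-fold higher, Gadd45b at least 7.47-fold and Cdca8 at least 6.89-fold. Of 24 measured genes of DNA replication 16 rose and 0 fell, and 19 rose when adjusted over the list alone, with Pcna 4.42-fold, Mcm4 5.77-fold and Rrm1 at least 5.92-fold higher. Of 20 genes of G2 and mitosis 14 rose, and 15 rose and 1 fell when adjusted over the list alone, with Kif20a at least 6.86-fold, Cdc20 5.95-fold and Birc5 5.64-fold higher. Both lists shifted upward (camera adjusted p = 1.2e-13 and 2.0e-11), with adjusted p = 0.061 and 0.083 with an estimated correlation. Mki67, a marker of cycling cells, was 2.57-fold higher (adjusted p = 0.026).

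Some genes that mark germinal centre B cells rose too. Bcl6, the transcriptional repressor that germinal centre B cells depend on, read 445 ± 9.90 in resting, 1322.5 ± 122 in TD day 4, 1441 ± 48.1 in TD day 10 and 940.0 ± 133 in TI day 4 (SD, n = 2 each). Its mean rise was 2.72-fold (adjusted p = 0.0021). The histone methyltransferase Ezh2 was at least 3.90-fold higher, Efnb1 at least 2.34-fold and Gcsam 3.18-fold on average, with no rise called in TI day 4. Of 11 measured genes of this list 5 rose and 1 fell, and 7 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.00072, adjusted p = 0.17 with an estimated correlation). Taken by group against resting, the list passed in TD day 4 and TD day 10 (camera adjusted p = 0.00013 and 0.00016). It did not pass in TI day 4 (camera adjusted p = 0.069). With an estimated correlation the camera adjusted p was 0.13, 0.11 and 0.36 in the same order. Of 18 genes of plasma cell differentiation and secretion 5 rose, also when adjusted over the list alone (camera adjusted p = 2.6e-05, adjusted p = 0.17 with an estimated correlation). Among them were Jchain, the chain that joins immunoglobulin polymers (4.41-fold), and the elongation factor Ell2 (3.50-fold). With each group set against resting separately, 11 of the 18 genes rose in TI day 4 and 2 in each TD group. In metabolism, 9 of 22 genes of oxidative phosphorylation rose, with Ndufs1 2.07-fold higher, and 8 of 23 MYC target and ribosome genes, with Npm1 2.50-fold higher. Adjusted over the list alone these were 9 risen, and 8 risen with 1 fallen. The camera adjusted p was 0.0021 and 0.0024, and adjusted p = 0.13 and 0.11 with an estimated correlation. Of 12 glycolysis genes 6 rose, also when adjusted over the list alone, with Pgk1 2.05-fold higher, while the whole list did not pass (camera adjusted p = 0.068).

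Many genes of resting and recirculating B cells fell. S1pr1, the receptor that guides lymphocytes out of lymphoid tissue, read 851 ± 122 in resting and 116.5 ± 26.2, 87.0 ± 14.1 and 95.0 ± 2.83 in TD day 4, TD day 10 and TI day 4 (SD, n = 2 each), a mean fall of at least 8.56-fold (adjusted p = 0.00048). The chemokine receptor Ccr7 was at least 6.45-fold lower, Klf3 4.24-fold and the IgE receptor Fcer2a 3.80-fold. Of 12 resting follicular genes 9 fell, and all 12 when adjusted over the list alone (camera adjusted p = 1.4e-10, adjusted p = 0.12 with an estimated correlation). Of 11 marginal zone and B1 genes 7 fell, 8 when adjusted over the list alone, with Notch2 at least 6.44-fold and Cd1d1 at least 3.65-fold lower (camera adjusted p = 4.1e-06, adjusted p = 0.11 with an estimated correlation). Of 17 genes of antigen presentation by MHC class II 6 fell, and 11 fell and 1 rose when adjusted over the list alone, with the protease Ctss 2.25-fold and H2-Oa 2.71-fold lower (camera adjusted p = 0.00018, adjusted p = 0.13 with an estimated correlation). Of 17 CD40 and NF-kB target genes 5 fell, also when adjusted over the list alone, with Nfkb2 at least 4.00-fold and Birc3 at least 2.95-fold lower. Of 21 genes of migration and adhesion 7 fell, and 8 fell and 1 rose when adjusted over the list alone, with Cd47 4.32-fold and Itgb7 1.89-fold lower. Each of these lists had a camera adjusted p of 0.023, and adjusted p = 0.13 with an estimated correlation. In cytokine signalling 2 of 16 genes fell, also when adjusted over the list alone, Stat6 at least 5.31-fold and the interleukin receptor chain Il4ra 3.90-fold. Esyt1 was at least 13.1-fold lower, Cnn3 at least 14.2-fold and the syndecan Sdc4 at least 7.14-fold.

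The remaining fixed lists did not pass as a whole between germinal centre and resting B cells. In B cell receptor signalling 1 of 19 genes rose and 5 fell, with the inhibitory receptor gene Fcgr2b 1.82-fold higher and Cd79b 1.61-fold lower (2 risen and 6 fallen when adjusted over the list alone). In DNA repair, hypermutation and class switching 2 of 11 rose, H2ax 3.41-fold and Chek1 1.60-fold (3 when adjusted over the list alone). In apoptosis 2 of 16 rose and 2 fell, with Bid at least 3.67-fold higher and Bcl2 2.02-fold lower (2 and 3 when adjusted over the list alone). In the type I interferon list 1 of 9 rose and 1 fell, Psmb9 1.60-fold higher and Irf9 at least 6.08-fold lower (1 and 2 when adjusted over the list alone). Of 17 immediate early genes 2 rose and 1 fell, with Fos 5.44-fold higher and Ier2 2.27-fold lower (2 and 3 when adjusted over the list alone). In TD day 4 alone the log2 difference of Fos from resting, 1.86 ± 0.66 (SE), did not pass. Of 18 B cell transcription factors 2 rose and 1 fell, Pou2af1 being 1.81-fold higher and Spib 1.65-fold lower, and of 7 immunoglobulin genes 2 rose, both counts holding when adjusted over the list alone.

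Some transcripts of other blood cells were higher in the resting arrays. The haemoglobin gene Hba-a1 read 14650.5 ± 1272 in resting and 381 ± 136, 571.5 ± 176 and 499 ± 12.7 in TD day 4, TD day 10 and TI day 4 (SD, n = 2 each), and Hbb-b2 was at least 63.3-fold lower in the germinal centre arrays. The neutrophil genes S100a8 and S100a9 were 7.43-fold and at least 8.29-fold lower, and the complement gene C1qa, made by macrophages, at least 7.42-fold. Of the marker lists, 4 of 7 red cell, 3 of 13 macrophage, 3 of 10 neutrophil, 1 of 9 T cell, 1 of 6 NK cell and 1 of 1 follicular helper T cell genes fell. Among 5 dendritic cell, 9 stromal and 2 platelet genes 0 changed, 1 of 4 plasma cell genes rose, and of 11 stress genes of cell sorting 2 rose and 1 fell. The red cell and macrophage lists shifted downward (camera adjusted p = 0.0032 and 0.018, adjusted p = 0.22 and 0.36 with an estimated correlation). Not all such genes were highest in resting: against resting alone, TI day 4 had 2 red cell genes higher and 3 lower, and 1 macrophage gene higher and 2 lower. In all, 960 probe sets differed between germinal centre and resting arrays, 561 higher and 399 lower (limma, adjusted p under 0.05), of which 948 remained without the red cell, granulocyte and macrophage markers. The count was 521 with array weights.

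**Figure D1:**
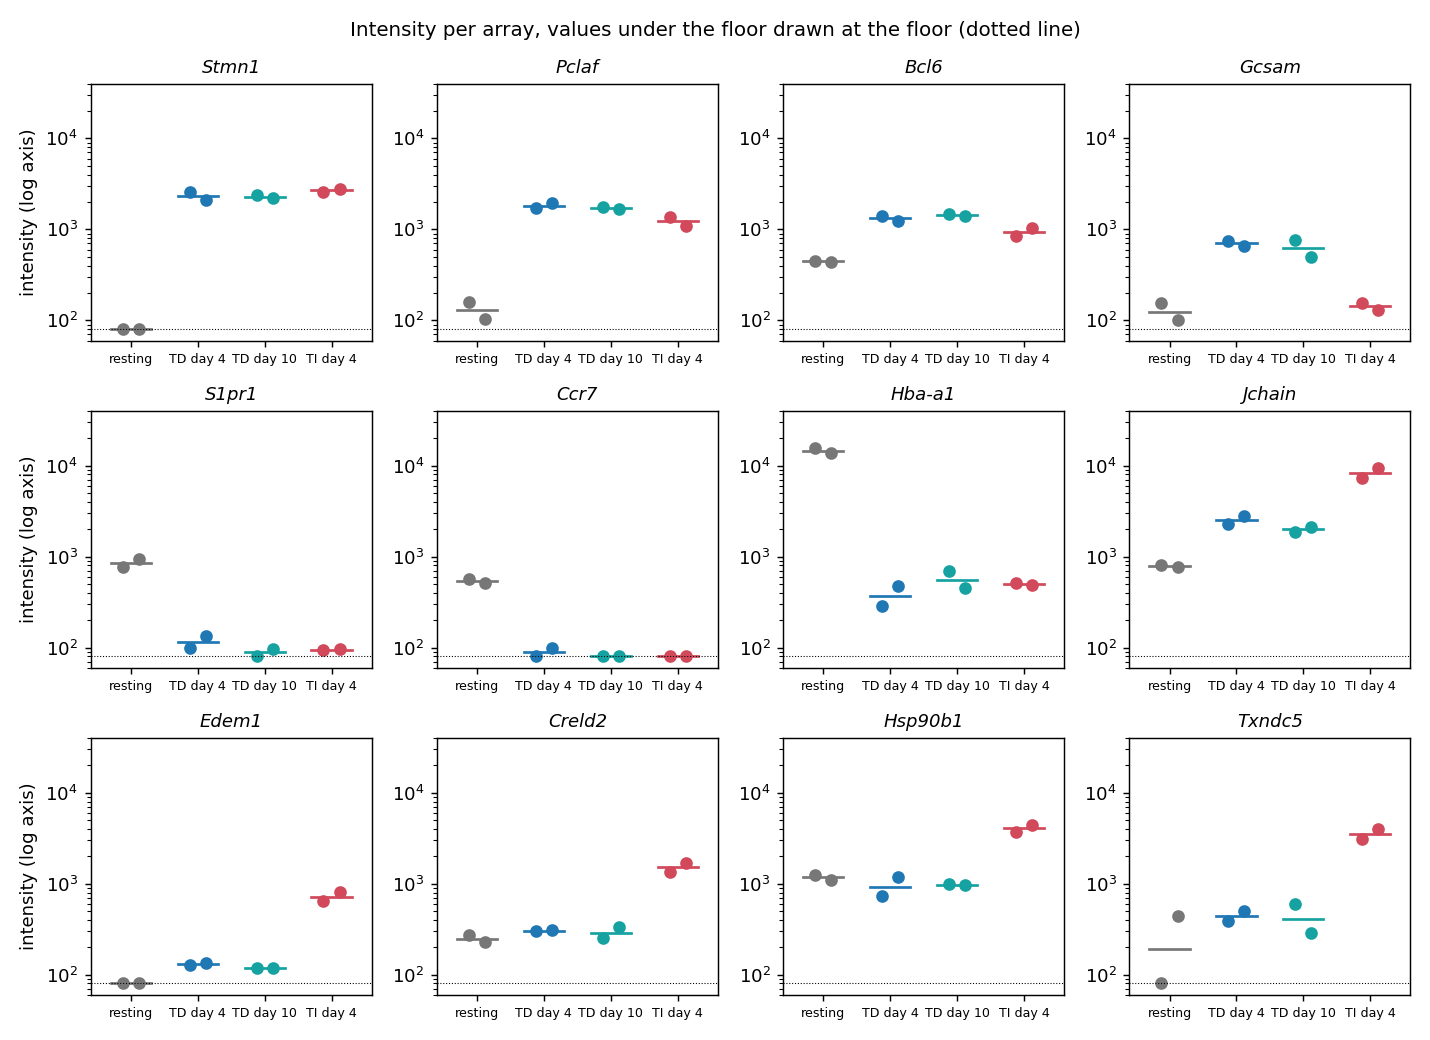
Intensity on a log axis for 12 genes, 1 panel per gene, with 1 point per array, a bar at the geometric mean of the 2 arrays of a group, and values under the floor of 81 drawn at the floor (dotted line). Stmn1, Pclaf and Bcl6 are higher in every germinal centre array than in the resting arrays, and Jchain, Edem1, Creld2 and Hsp90b1 are highest in the TI arrays.

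Each germinal centre group was also set against resting B cells separately. Stmn1, Anxa2 and Hmgb2 were among the 10 largest rises in each, Stmn1 by at least 28.7-fold in TD day 4, 28.3-fold in TD day 10 and 33.3-fold in TI day 4. Bcl6 was 2.97-fold, 3.24-fold and 2.10-fold higher, and S1pr1 7.36-fold, at least 9.55-fold and 8.91-fold lower, in the same order. Gcsam was 5.66-fold higher in TD day 4 and 4.97-fold higher in TD day 10, and in TI day 4 its log2 difference was 0.20 ± 0.30 (SE) and did not pass (adjusted p = 0.77). In TI day 4 the largest rises included the heat shock genes Hspa1a (at least 24.5-fold) and Hspa1b (18.5-fold), the immediate early gene Fos (13.7-fold) and Txndc5, an oxidoreductase of the endoplasmic reticulum (at least 18.3-fold). Of 11 stress genes of cell sorting 3 rose in TI day 4, also when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.39), while 0 rose and 1 fell in each TD group. Between TI day 4 and TD day 4, 0 of these 11 genes passed, also when adjusted over the list alone (camera adjusted p = 0.40), and the list median against resting was 0.36 in TI day 4, 0.63 in TD day 4 and 0.53 in TD day 10. Between TI day 4 and TD day 10 also 0 passed, with 2 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.23). Plasma cell markers shifted upward in TI day 4 with 3 of 4 called, also when adjusted over the list alone (camera adjusted p = 0.012, adjusted p = 0.45 with an estimated correlation). Of 18 genes of plasma cell differentiation and secretion 11 rose in TI day 4, 14 when adjusted over the list alone (camera adjusted p = 1.2e-11, adjusted p = 0.15 with an estimated correlation). In TD day 4 and in TD day 10 the count was 2, and 3 when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.058 and 0.19).

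In all, 683 probe sets differed from resting in TD day 4 (423 higher), 790 in TD day 10 (468 higher) and 682 in TI day 4 (393 higher). Those called in the same direction in all 3 numbered 376, 225 higher and 151 lower. Simulations without any effect, in which the groups shared the resting arrays, gave 101.8. There the same number of probe sets with the smallest p was taken per comparison, whether or not they passed. TD day 4 and TD day 10 shared 590 calls of the same direction (220.7 in simulation). TI day 4 shared 408 with TD day 4 (201.7 in simulation) and 408 with TD day 10 (218.9 in simulation). The 2 resting arrays were not divided between the comparisons, so the shared calls rest on the same controls. With only the arrays compared in the fit, the counts were 118, 195 and 100, and with array weights TD day 10 gave 511 and TI day 4 454. Without TD day 4 replicate 1 or 2 the TD day 4 count was 192 or 241, without TD day 10 replicate 1 or 2 the TD day 10 count was 297 or 322, and without TI day 4 replicate 1 or 2 the TI day 4 count was 334 or 308. Scaling the arrays to a common median moved the median log2 difference of TD day 10 by -0.12 and gave 364 higher and 392 lower.

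The comparison of TI with TD germinal centre B cells on day 4 paired responses that the series design describes as having comparable kinetics. Some genes of the secretory pathway were higher in TI. Edem1, which sends misfolded glycoproteins to degradation, read 721 ± 116 in TI and 130.5 ± 3.54 in TD day 4 (SD, n = 2 each), a rise of 5.49-fold (adjusted p = 0.0067). Creld2 and the chaperone Hsp90b1, both of the endoplasmic reticulum, were 4.99-fold and 4.35-fold higher. Jchain read 8351.5 ± 1421 against 2518 ± 356, a rise of 3.31-fold (adjusted p = 0.021). Of 18 genes of plasma cell differentiation and secretion 6 rose and 0 fell, and 12 rose when adjusted over the list alone, with a median log2 difference of 1.35 (camera adjusted p = 4.3e-13, adjusted p = 0.22 with an estimated correlation). Other rises were Man1b1, a mannosidase (at least 5.61-fold), H13, a signal peptide peptidase (8.27-fold), the exonucleases Rexo2 (6.06-fold) and Isg20 (4.45-fold), Cd302 (at least 5.34-fold), Nadk, the kinase that makes NADP (at least 10.9-fold), and Rap1gap (at least 7.37-fold). In B cell receptor signalling the transcription factor gene Nfatc1 rose 2.41-fold, the 1 gene called of 19, with 4 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.020, adjusted p = 0.29 with an estimated correlation).

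Gcsam, an adaptor of germinal centre B cells, read 143.5 ± 17.7 in TI and 707 ± 65.1 in TD day 4 (SD, n = 2 each), a fall of 4.94-fold (adjusted p = 0.028). It was the 1 gene called of the 11 of the germinal centre list, or 1 of 2 lower when adjusted over the list alone (camera adjusted p = 0.013, adjusted p = 0.49 with an estimated correlation). The log2 difference of Bcl6 was -0.50 ± 0.17 (SE) and did not pass (adjusted p = 0.26). The protease inhibitor Slpi was 7.83-fold lower, the lysosomal sulfatase Ids 6.70-fold and the DNA repair endonuclease Apex1 2.26-fold. Basp1 was 8.22-fold lower at 1 probe set, and at its brighter probe set the log2 difference was -0.65 ± 0.21 (SE) and did not pass. In the MYC target and ribosome list 0 of 23 genes passed and 1 was lower when adjusted over the list alone (camera adjusted p = 0.020, adjusted p = 0.22 with an estimated correlation). In DNA replication and in G2 and mitosis 0 genes passed, and the log2 difference of Mki67 was -0.11 ± 0.34 (SE, adjusted p = 0.97).

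The TI arrays also read higher than the TD day 4 arrays in the 3' to 5' control ratios, read here as RNA quality. The difference in these ratios was not tested. Some lists of markers of other cells were higher too. The ratio of 3' to 5' Gapdh signal was 1.46 ± 0.308 in TI, 0.968 ± 0.0192 in TD day 4, 0.866 ± 0.0426 in TD day 10 and 1.23 ± 0.510 in resting (SD, n = 2 each). That of actin was 1.75 ± 0.225 in TI, 1.41 ± 0.103 in TD day 4, 1.30 ± 0.0842 in TD day 10 and 1.72 ± 0.232 in resting (SD, n = 2 each). The 18S RNA control read 5172.5 ± 347 in TI and 2190 ± 662 in TD day 4 (SD, n = 2 each). The BioDn-3 control read 555.5 ± 50.2 and 8.50 ± 179 in the same order (SD, n = 2 each). A technical difference behind these controls would coincide with the TI group and could not be told apart from the response. Macrophage markers shifted upward with 0 of 13 called (camera adjusted p = 0.0013), and plasma cell markers with 1 of 4 called (camera adjusted p = 0.00018), with adjusted p = 0.33 with an estimated correlation for each. Of 7 red cell genes 1 rose, 2 when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.40). Several of the largest changes were seen at 1 of the gene's probe sets. The log2 difference of Hnrnpu was 4.09 at 1 probe set and at most -0.52 at another, that of Tnnt1 at least 3.83 and -0.32, and that of Cmc2 2.96 and -0.27, with only the first of each passing. Other probe sets of Slpi and Ids did not pass either. Of 49 other probe sets of the genes called, 37 had the same direction, 6 were called in that direction and 0 in the opposite one.

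In all, 105 probe sets differed between TI and TD day 4, 53 higher and 52 lower (limma, adjusted p under 0.05), and 87 remained without the immunoglobulin probe sets. The count was 0 with only the arrays compared, 0 with the Gapdh ratio as a covariate, 42 without the filter, 46 with a replicate block, 261 with array weights, 1 or 7 without TD day 4 replicate 1 or 2, 22 without either TD day 10 array, and 28 or 0 without TI day 4 replicate 1 or 2. The list count of 5 became 8 without TD day 4 replicate 2 and 2 with the covariate.

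**Figure D2:**
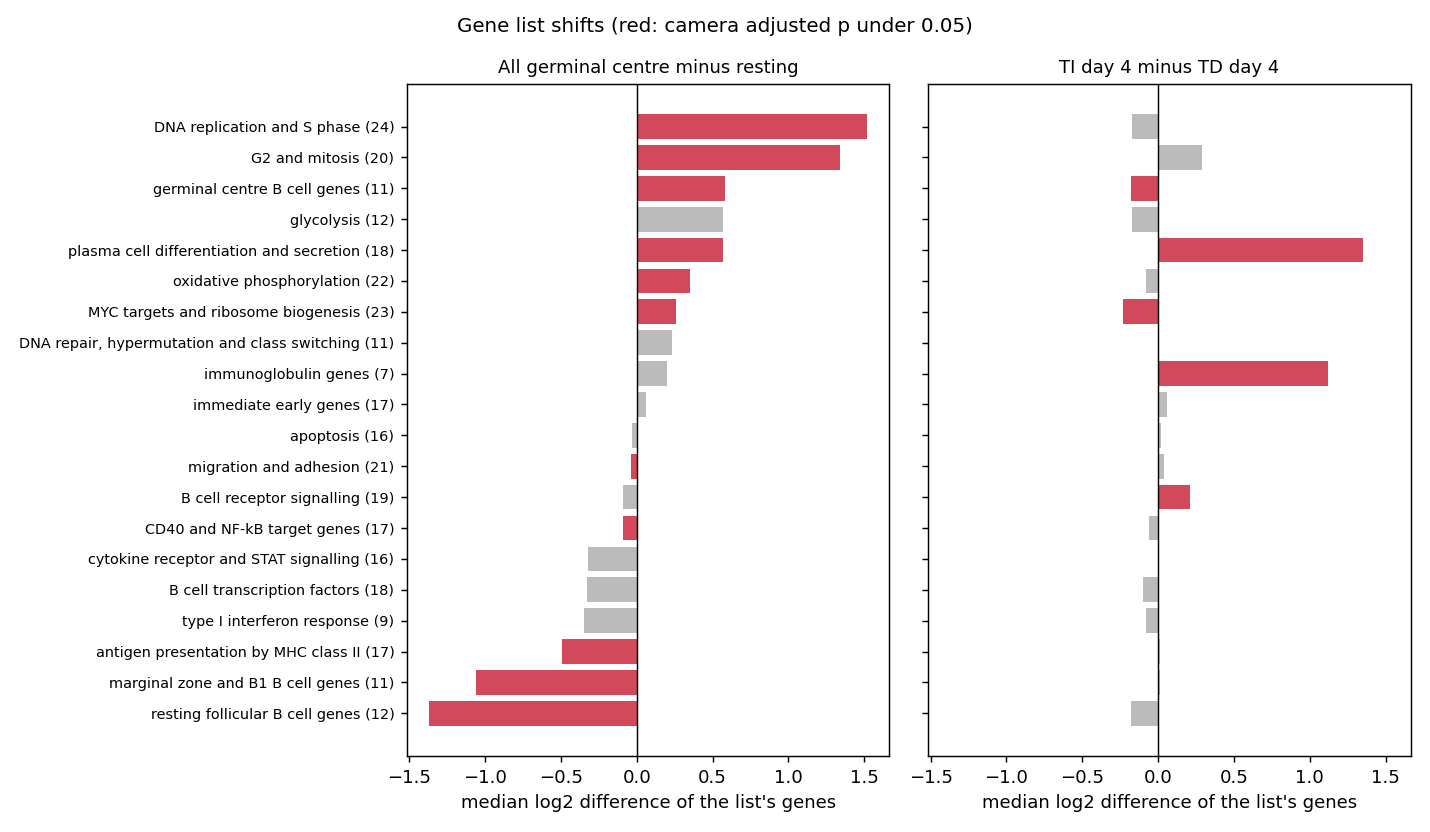
Median log2 difference of each of 20 gene lists fixed before the data were examined, for all germinal centre minus resting arrays (left) and TI day 4 minus TD day 4 (right), with the number of measured genes in brackets. Red bars had a camera adjusted p under 0.05 at a preset correlation of 0.01; DNA replication has the highest median on the left (1.52) and plasma cell differentiation and secretion on the right (1.35).

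Immunoglobulin probe sets moved in opposite directions between TI and TD. The kappa variable gene Igkv6-14 was at least 18.8-fold lower in TI than in TD day 4, Igkv10-96 9.49-fold, Igkv4-68 6.53-fold and Igkv14-111 at least 6.13-fold. The heavy chain variable gene Ighv3-6 was at least 5.80-fold lower. Of 32 light chain probe sets tested, 11 fell and 1 rose against TD day 4, and 12 fell and 2 rose against TD day 10. The one that rose in both carries the lambda symbols Iglc1 and Iglv1 and was chosen after its values were seen. Its log2 difference was 2.67 from TD day 4 and 4.03 from TD day 10 (adjusted p = 0.0067 and 0.0015). The probe set named Iglc1 alone had log2 differences of at most -1.31 and at most -1.18 ± 1.08 (SE) and did not pass. Igkv9-120 read 21460.5 ± 968 in TI, 1581 ± 453 in TD day 10 and 5142.5 ± 4317 in resting (SD, n = 2 each), a rise of 13.9-fold over TD day 10 (adjusted p = 0.037), while its other probe set had a log2 difference of -0.64. Igll1, a surrogate light chain gene, was 2.61-fold higher in TI than in TD day 4. With Jchain it made 2 of 7 immunoglobulin genes risen, 4 when adjusted over the list alone (camera adjusted p = 0.00086, adjusted p = 0.22 with an estimated correlation). The brightest Ighm probe set read 26408 ± 304 in TI, 16082 ± 1660.3 in TD day 4 and 10219.5 ± 1875 in TD day 10 (SD, n = 2 each), with log2 differences of 0.72 from TD day 4, which did not pass, and 1.38 from TD day 10 (adjusted p = 0.027). It was the highest signal of each TI array, and whether it was saturated is not known, so these differences may be too small. A dimmer Ighm probe set had log2 differences of 0.77, which did not pass, and 1.60 (adjusted p = 0.012). Probe sets named Ighg3 moved apart, 1 having a log2 difference of 1.41 from TD day 4 that did not pass and another of -3.93 that did (adjusted p = 0.046). Immunoglobulin probe sets share sequence between genes, so which gene each one reads is uncertain.

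**Figure D3:**
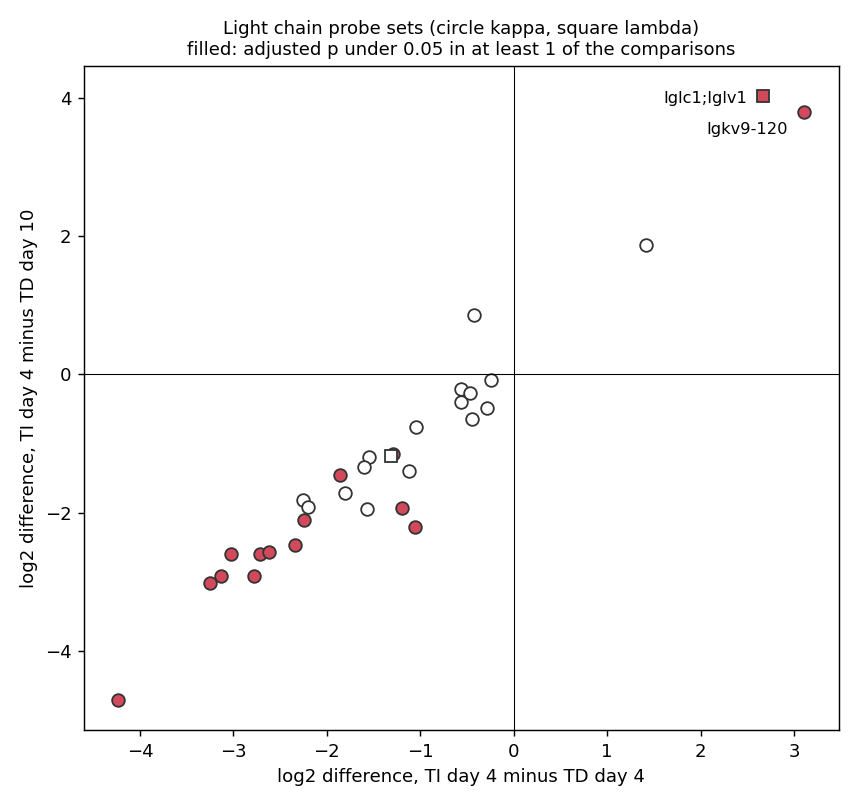
Log2 difference of 32 light chain probe sets, TI day 4 minus TD day 4 on the horizontal axis and TI day 4 minus TD day 10 on the vertical axis. Circles are kappa and squares lambda, and filled symbols had an adjusted p under 0.05 in at least 1 of the comparisons; the lambda probe set of Iglc1 and Iglv1 and a probe set of Igkv9-120 lie at the upper right.

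Against TD day 10, TI germinal centre B cells again had more transcript of some secretory genes. Edem1 was 6.07-fold, Creld2 5.21-fold, Jchain 4.17-fold and Hsp90b1 4.15-fold higher. Of 18 genes of the plasma cell and secretion list 6 rose and 14 rose when adjusted over the list alone (camera adjusted p = 1.3e-13, adjusted p = 0.14 with an estimated correlation). Markers of other cells moved as well. Plasma cell markers shifted upward with 2 of 4 called, 3 when adjusted over the list alone, and macrophage markers with 1 of 13 called, also when adjusted over the list alone (camera adjusted p = 0.00031 and 0.0067, adjusted p = 0.35 with an estimated correlation for each). In lists that did not pass, 1 of 5 dendritic cell and 1 of 7 red cell genes rose, 1 and 2 when adjusted over the list alone. Of 7 immunoglobulin genes 3 rose, 4 when adjusted over the list alone, and of 19 B cell receptor signalling genes 2 rose, Nfatc1 3.97-fold and Cd81 2.00-fold, or 5 when adjusted over the list alone (camera adjusted p = 3.4e-05 and 0.00046, adjusted p = 0.14 with an estimated correlation for each). Gcsam was 4.34-fold lower, the 1 gene called of 11, or 1 of 3 lower when adjusted over the list alone (camera adjusted p = 0.014, adjusted p = 0.42 with an estimated correlation). The glutathione transferase Gsta2 was at least 33.6-fold higher, Slc4a1, the anion exchanger of red cells, 8.41-fold, and Cd9 at least 4.27-fold. The steroid dehydrogenase Hsd3b5 had a log2 difference of 3.91 ± 0.34 (SE). Nfkb2 was at least 3.36-fold lower and Gpn2 at least 5.17-fold. The G2 and mitosis list shifted upward and the MYC target list downward with 0 genes called in either, and 0 and 6 when adjusted over the list alone (camera adjusted p = 0.030 each, adjusted p = 0.42 and 0.21 with an estimated correlation).

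In all, 174 probe sets differed between TI and TD day 10, 87 higher and 87 lower. Of these, 92 had been called in the same direction against TD day 4, a comparison that shares the TI arrays. Taking as many probe sets with the smallest p in simulations without any effect gave 29.7, and 1.26 are expected of independent lists. The 2 TI arrays were not divided between the comparisons, so part of this overlap may come from sharing them. Scaling to a common median moved the median log2 difference by 0.14 and gave 118 higher and 77 lower. The count was 0 with only the arrays compared, 104 without the filter, 107 with a replicate block, 292 with array weights, 7 with the Gapdh ratio as a covariate, 78 without either TD day 4 array, 4 or 16 without TD day 10 replicate 1 or 2, and 45 or 23 without TI day 4 replicate 1 or 2.

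TD day 10 was compared with TD day 4 to set the unprimed against the primed T-dependent response, which also differ in day and adjuvant. Of 7253 probe sets 0 passed in limma, 373 had an unadjusted p under 0.05 where 362.7 are expected by chance, and an equal-variance test of each probe set alone also gave 0 with 462 unadjusted. The smallest adjusted p was 0.14. Among the genes with the smallest p, Prpf19 had a log2 difference of at least 1.84 ± 0.18 and Inhba, a subunit of activin, of -1.30 ± 0.17 (SE), neither passing. Inhba read 305 ± 38.2 in TD day 10 and 750.5 ± 24.7 in TD day 4 (SD, n = 2 each). The resting follicular and B cell receptor lists each had a camera adjusted p of 0.043, with adjusted p = 0.79 with an estimated correlation and 0 genes called, also when adjusted over the list alone. Without the filter 14 probe sets passed and without TD day 4 replicate 2 there was 1, while the 2 lists became 5 without TD day 4 replicate 1 and 0 without either resting array, TD day 4 replicate 2 or either TD day 10 array.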

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

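All tests in this part were chosen after the results were seen, apart from the limma tests of the differences.

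Some probe sets changed against resting B cells in opposite directions in TI and TD germinal centre B cells. Nadk rose in TI day 4 and fell in both TD groups, and the TI value exceeded the TD day 4 value by at least 3.45 and the TD day 10 value by at least 3.57 on the log2 scale (limma, adjusted p = 0.018 and 0.011). Slc4a1 rose in TI day 4 and fell in TD day 10, a difference of 3.07 (limma, adjusted p = 0.0040). The probe set of Iglc1 and Iglv1 rose in TI day 4 and fell in TD day 10, a difference of 4.03 (limma, adjusted p = 0.0015).

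Control probe sets outside the comparisons also differed from resting. The MurFAS control read 406 ± 2.83 in TD day 4, 421.5 ± 16.3 in TD day 10 and 232.5 ± 0.707 in TI day 4, against 106.5 ± 53.0 in resting (SD, n = 2 each). By its name this control reads Fas, a gene of the germinal centre list fixed before the data were examined. As a control probe set it was left out of the tests. The BioDn-3 control read 555.5 ± 50.2 in TI day 4, against 46.5 ± 33.2 in resting, 8.50 ± 179 in TD day 4 and -271 ± 182 in TD day 10 (SD, n = 2 each). Both TI arrays, at 520 and 591, read above all others, of which the highest was 135. What raised the BioDn-3 signal in the TI arrays was not tested.

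The light chain probe sets form a pattern in which 2 of 32 were higher and 12 lower in TI day 4 than in TD day 10. More immunoglobulin transcript of every kind would raise most of them, which the 12 lower ones argue against. A single rising transcript read by all cross-hybridising kappa probe sets would raise the other 16 kappa probe sets whose names end in _f_at, and of these 8 were called lower and 0 higher. A candidate explanation that stays open is a different use of light chain genes by the cells sorted in the TI response, a hypothesis that was not tested, since sequence shared between probe sets leaves the gene behind each signal uncertain.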

How the results depend on the processing

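The 3' to 5' Gapdh covariate, the floors at the 40th and 60th percentiles, the pseudocount, the crossed replicate block, and leaving out marker or immunoglobulin probe sets were chosen after seeing the data; the other settings were planned. A floor at the 15th percentile and a pseudocount at the 30th were not run, since these percentiles are -69 and 0. Signal over background limits dim genes, with 30.1% of values 0 or below. The rule named 787 gene results, tested in up to 22 settings each. Of 380 past the threshold 63 stayed past it in every setting and 317 lost it in at least 1. All 380 kept their direction in every setting. Several settings cannot change the log2 difference, so a kept direction tests nothing there. These are the filters, the replicate blocks, only the arrays compared, the changed prior and each probe set tested alone. Leaving out an array of a group not compared is another. Of 407 that had not passed, 49 changed direction in at least 1 setting. Among those in the text, Mki67 in TI day 4 against TD day 4 was 0.52 with the covariate and from -0.38 to 0.17 without 1 array, against -0.11, and the Iglc1 probe set was 0.66 against TD day 4 and 1.32 against TD day 10 with the covariate. Outside the results named by the rule, Gcsam in TI day 4 against resting was 0.50 or -0.11 without resting replicate 1 or 2, against 0.20.

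Counts of probe sets follow where they moved by over 1.5 times, and except where fewer arrays were fitted the cause was not tested. TI day 4 against TD day 4 gave 105, and 42 without the filter, 46 with a replicate block, 27 with a crossed block, 261 with array weights, and 0 with only the arrays compared, with the covariate or with each probe set tested alone. TI day 4 against TD day 10 gave 174, and 104 without the filter, 107 with the block, 292 with weights, 7 with the covariate, 9 with each probe set alone and 0 with only the arrays compared. TD day 10 against TD day 4 gave 0, and 1 and 8 with floors at the 40th and 60th percentiles and 14 without the filter. Germinal centre against resting gave 960, and 521 with weights. TD day 4 against resting gave 683, and 118 with only the arrays compared and 19 with each probe set alone. TD day 10 against resting gave 790, and in the same order 195 and 43, with 511 with weights and 491 with the covariate. TI day 4 against resting gave 682, and 100 and 21, with 434 without the filter and 454 with weights. Under the replicate block, the counts against resting were 723 for all germinal centre arrays, 489 for TD day 4, 588 for TD day 10 and 517 for TI day 4.

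Without each array in turn, where the lone array is assumed to vary like the other groups, counts ranged from 0 to 125 for TI day 4 against TD day 4, 0 to 1 for TD day 10 against TD day 4, 4 to 245 for TI day 4 against TD day 10 and 641 to 789 for germinal centre against resting. They ranged from 192 to 621 for TD day 4, 297 to 863 for TD day 10 and 308 to 675 for TI day 4 against resting. The lists past the threshold, 5, 2, 6, 11, 11, 13 and 9 over the comparisons, were 0 in each with an estimated correlation. With fry they were 12 for TI day 4 against TD day 10, 17 for germinal centre against resting and 15 for TI day 4 against resting. With the covariate they were 2 for TI day 4 against each TD group. The 2 lists of TD day 10 against TD day 4 were 0 under the block, quantile normalization, fry and the covariate. Without 1 array they ranged from 4 to 8 for TI day 4 against TD day 4 and from 0 to 5 for TD day 10 against TD day 4.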

Other observations

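All tests of an explanation in this part were chosen after the results were seen.

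Some genes with large changes against resting B cells have not been described. The fatty acyl-CoA binding protein gene Dbi rose 7.23-fold in TD day 4 and 7.37-fold in TD day 10. In TD day 10 the transcription factor subunit gene Tfdp1 rose at least 7.60-fold and Rpa3, of the single-strand DNA binding complex, 7.17-fold. The lipid transporter gene Abcg1 was at least 9.28-fold lower in TD day 4 and in TD day 10. In TI day 4 Emp3 was 10.5-fold lower and Nifk at least 11.7-fold lower.

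Other probe sets of a called gene were called in the same direction in 34.3% of 315 cases for germinal centre against resting, in 12.2% of 49 for TI day 4 against TD day 4 and in 10.5% of 76 for TI day 4 against TD day 10, and 0 were called in the opposite direction. Probe sets named Adck1 were at least 10.3-fold lower in TI day 4 than in TD day 4 and at least 14.4-fold lower than in TD day 10, and both have names ending in _f_at, so the gene they read is uncertain.

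Genes of plasma cell differentiation and secretion tended to be higher in TI day 4 than in TD day 4, with a list median of 1.35 and a list mean of 1.28 on the log2 scale (95% t interval of the list mean per array 0.762 to 1.80; adjusted p = 0.22 with an estimated correlation). With quantile-normalized values the median was 1.34 and the mean 1.28 (95% interval 0.795 to 1.76), with the lower limit above 0.641, 0.5 times the mean without it, which argues against array scaling as the whole cause. With the Gapdh ratio as a covariate the median was 1.44 and the mean 1.29 (95% interval 0.389 to 2.18; camera adjusted p = 6.7e-10, adjusted p = 0.48 with an estimated correlation). The mean did not fall with the covariate and its interval lies above 0. The slope of the covariate rests only on differences within groups, with 3 residual degrees of freedom, so the fit cannot decide on RNA quality. The lower limit is also under 0.641, and RNA quality stays open as a cause of the rise. Of the 6 genes called, 0 stayed called. Their calls ended with those of all 105 probe sets as the residual degrees of freedom went from 4 to 3, the median size of these from 1.91 to 1.71 and their median SE from 0.204 to 0.240. Plasma cells inside the gate could give the same pattern and cannot be told apart from secretory genes in the germinal centre B cells themselves, since Jchain, a marker of both, rose by 1.73, B220 staining may remove plasma cells only in part, and resting B cells already read 783.5 ± 27.6 for it (SD, n = 2).

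Some red cell, granulocyte and macrophage genes were higher in resting arrays. Of the 30 measured genes of these lists 33.3% were lower in the germinal centre arrays, against 5.36% of all genes, while 2 red cell genes and 1 macrophage gene were higher in TI day 4 than in resting. Cells of other types in the resting sort could give this and stay open, since the lists were joined because their genes had fallen, so the count does not test it, and the B220 gate would remove such cells. Resting cells came from unimmunised mice, and a difference from immunised mice was not tested. Whether a lower share of B cells raised every other marker alike stays open: the median log2 difference was 0.11 for T cells and -1.05 for red cells, a gap of 1.16 (exact permutation p = 0.092 over 11440 splits).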
